A study of Mus musculus with 2 samples.

How the data were processed

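RNA was sequenced from 2 cultures of 46C mouse embryonic stem cells, a line that carries green fluorescent protein in the Sox1 locus. The library titled PB and the library titled PB-Gbx2 each stood for 1 vector, so there was 1 library per group and no replicate. Per the labels' protocols, cells were kept on gelatin in serum medium with LIF, RNA was taken with Trizol, and libraries were made with a TruSeq RNA kit. The titles and the source names in the labels contradict each other: the library titled PB has the source name of Gbx2-overexpressing cells, and the library titled PB-Gbx2 that of the empty-vector control. Groups follow the titles, because the titles match the vector names in the series title and the column names of the table. If the source names were right instead, every direction given here would turn around.

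Reads were handled with STAR and the mouse build mm9, per the submitters' processing notes, and their versions, the annotation and the counting tool are not given in the sources used here. The deposited table has 14501 rows, each with a gene symbol and no identifier or coordinate, so no genomic positions are given. The level of a gene in each library is a whole number that the authors normalized and rounded, and it was treated as a score and not as a read count. The reason is that the sorted values of both libraries are the same in every one of the 14501 rows, with a total of 16528899 and a median of 388 in each, as after quantile normalization. The 10 highest genes of each library share the value 70328, the next 10 lie between 45096 and 45185, and the next 10 between 31024 and 31076. A step of 1.56-fold and then 1.45-fold separates these blocks, so ratios of the most abundant genes are coarse. No row has a mean level under 8. Read counts and depth are unknown, so no counting interval or detection floor could be given. Any difference in the overall distribution between the libraries was removed by this step and cannot be seen in these values.

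The authors' deposited table also holds their ratio and the log2 of that ratio, which equal PB over PB-Gbx2 (within 1e-06 for the ratio), and their p-value with an adjusted p-value. The adjusted values deviate by at most 3.8e-05 from Benjamini-Hochberg adjustment over all rows. The authors' p-values rest on 1 library per group and are quoted only as theirs. Of the symbols, 21 read as a calendar date, a conversion made by spreadsheet programs, and these genes are not named. The 2 rows that share such a symbol were summed, which left 14500 symbols. All columns of the table belong to the 2 libraries.

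The plan had assumed FPKM-like values, and its measure was kept because it suits any level on a linear scale. The log2 ratio of PB-Gbx2 over PB was computed on log2(level + 1), which understates the change of genes with low levels. A gene was called at least 2-fold higher or lower where this ratio reached 1 or -1, with a level of at least 1 in either library. With 1 library per group there is no test between conditions, and no p-value was computed. Fold changes in the text are ratios of the deposited levels. For each gene, its place among the genes in the same twentieth of mean level was recorded as a percentile. Before the data were examined, 31 gene lists were fixed. For each, the median log2 ratio of its listed members was placed among the medians of 10000 random lists with as many genes from each twentieth of mean level. This percentile describes these 2 libraries and is not a test of the vectors. Random lists are made of unrelated genes, while members of a pathway vary together between any 2 cultures. Of the listed genes, 32 belong to more than 1 list.

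Genes were named by a rule fixed in advance: Gbx2, the 12 largest ratios in each direction among genes at a level of at least 5 in either library without predicted gene models, a set of pluripotency and lineage genes, and up to 4 members of each list with the largest absolute ratio. Genes taken from the authors' adjusted p-values, and a few further members of lists, were chosen after their values were seen. Fgf5 and Cdx2 were in the rule but have no row in the table and were not analysed here. A few genes that the rule covers are not reported here. Alternatives were a pseudocount of 0.1 or 5, a minimum level of 5 or none, rescaling by the median or by a trimmed mean (30 percent from each side), a 1.5-fold threshold and the highest row kept per symbol. The list procedure was tested on simulated data made by shuffling the ratios of the 14500 genes within level bins. Of 200 lists of 20 genes with no shift, 1 lay above and 6 below the middle 95 percent of random lists. Shuffling removes the joint variation of pathway members, so this rate does not carry over to the real lists. With a log2 shift of 0.25, 135 of 200 lists lay above it, and with a shift of 0.5, 198 of 200. GC content and length came from the longest GENCODE M21 transcript of each symbol, matched for 14160 genes (97.7%). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.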

Results

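The transcriptome of 46C mouse embryonic stem cells transfected with a Gbx2 vector was compared with that of cells transfected with the empty vector, to find which genes differ when this homeobox transcription factor is overexpressed in serum medium with LIF. The table lists 14500 gene symbols in the library titled PB (empty vector) and the library titled PB-Gbx2. Each group has 1 library, so the values have no replicate error, and a difference between the 2 libraries was compared only with the spread of other genes of similar level. The log2 ratios of all genes had a median of 0 and an SD of 0.65. When genes were split into 10 groups of equal size by level, the SD was 1.15 in the lowest group (median level 18.5) and 0.32 in the highest (median level 4193). At low levels, a 2-fold difference thus does not by itself set a gene apart. Some genes reported below as past 2-fold lay inside the spread of genes of similar level. Examples are T (percentile 89.7), Gata6 (92.1), Fst (96.6), Dlk1 (86.1) and Car9 (6.3). Others, such as Sox1 (99.2) and Kdr (99.9), lay further out. Where a gene is followed by a pair of levels, the first is that in PB and the second that in PB-Gbx2.

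Gbx2 stood at a normalized level of 345 in the PB library and 1178 in the PB-Gbx2 library, 3.41-fold higher in the latter. Its ratio lay at percentile 99.9 among genes of similar level. This direction goes with the titles of the libraries and against their source names. In the authors' deposited table the adjusted p of Gbx2 is 0.0146. The files do not separate reads of the vector from reads of the endogenous gene.

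Across the transcriptome, 746 genes were at least 2-fold higher and 762 at least 2-fold lower in the PB-Gbx2 library. Most of them had low levels: among the 10941 genes that reached a level of 100 in either library, 269 were higher and 259 lower, and among the 4253 that reached 1000, 46 and 38. The authors' deposited table gives 34 genes an adjusted p under 0.05, 21 of them higher in PB-Gbx2 and 13 higher in PB. Those higher in PB-Gbx2 include Bhmt (28 to 572), which transfers a methyl group from betaine to homocysteine, Dmgdh (45 to 508), a mitochondrial dimethylglycine dehydrogenase, the SoxB2 transcription factor Sox21 (44 to 658), the carnitine carrier Slc25a20 (640 to 3082), the adenylate kinase Ak4 (1564 to 6096) and the aquaporin Aqp3 (380 to 1634). Those lower in PB-Gbx2 include the mitophagy receptor Bnip3 (6018 to 1621), the kinesin Kif21b (2176 to 548), Porcn (1168 to 251), which acylates Wnt proteins, Anxa2 (1988 to 569), Emb (982 to 234) and the desaturases Scd1 (3010 to 1114) and Scd2 (9088 to 3882).

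By ratio alone, the 12 genes highest in PB-Gbx2 were Tdpoz3, Bhmt, Scn4b, Msc, Wnt5a, Sox21, Pou3f3, Zhx2, Ms4a10, BB287469, Aspa and Sec1. The signalling ligand Wnt5a went from 10 to 170 and the bHLH repressor Msc from 8 to 156. Tdpoz3, Scn4b, Pou3f3, Zhx2, Ms4a10, BB287469, Aspa and Sec1 had a level of 1 or 2 in the PB library and at most 69 in the other, where ratios scatter widely. The 12 lowest were Slc7a11, Anxa11os, Fam196b, Hist3h2ba, Rsph9, Hsf4, Il33, Slc45a1, Scn9a, Alox12b, Lrtm2 and Krt7. Slc7a11, the cystine transporter subunit, went from 87 to 2, and Slc45a1 from 107 to 10. The other 10 stood at 66 or less in PB and at 6 or less in PB-Gbx2.

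Genes of the naive pluripotency network were higher on balance in the PB-Gbx2 library. Klf4, a LIF-responsive Kruppel-like factor, stood at 4701 and 10924 (2.32-fold higher), Tbx3 at 3029 and 6107 (2.02-fold), Zfp42 (Rex1) at 8320 and 16671, Prdm14 at 256 and 570 (2.23-fold) and Spic at 62 and 258 (4.16-fold). Of the 22 listed members, 6 were at least 2-fold higher, none was 2-fold lower, 15 lay above 0 and 7 below. The median log2 ratio was 0.53, above all 10000 matched random lists. Not all members shared the direction: Klf5 was 1.66-fold lower (1808 to 1092), while Tfcp2l1 (12900 and 11892) and Esrrb (7508 and 9456) differed by less than 1.3-fold, and Klf2 was 1.49-fold higher. In the authors' deposited table Klf4 has an adjusted p of 0.0421, Zfp42 0.162, Tbx3 0.211, Spic 0.355 and Prdm14 0.874.

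The core factors Pou5f1 (9446 and 10597) and Sox2 (9894 and 10302) differed by at most 1.12-fold, whereas Nanog was 2.23-fold higher in PB-Gbx2 (8918 to 19872), with an adjusted p of 0.054 in the authors' deposited table. Fbxo15 (2.08-fold) and Gdf3 (2.04-fold) were also higher, and Epcam was 1.59-fold lower. The general pluripotency list had 3 of 18 members at least 2-fold higher, none lower, and a median of 0.04, inside the middle 95% of random lists. Dnmt3b, the de novo DNA methyltransferase that marks the transition out of the naive state, was 2.44-fold lower in PB-Gbx2 (4290 to 1761), and its adjusted p in the authors' deposited table is 0.0439. The formative and primed list as a whole (20 members) had a median of -0.20 at percentile 4.29 but a mean of 0.22: Dnmt3b and Krt18 were at least 2-fold lower, Otx2 was 1.32-fold lower, and Foxd3 (134 to 538), Sox3 (3 to 30) and Fst (6 to 44) were higher. In the DNA methylation list (11 members, median -0.14, percentile 7.02), Dnmt3b was the sole member that differed 2-fold. Dnmt3a was 1.25-fold and Dnmt3l 1.22-fold lower, and Zfp57 was 1.69-fold higher.

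**Figure D1:**
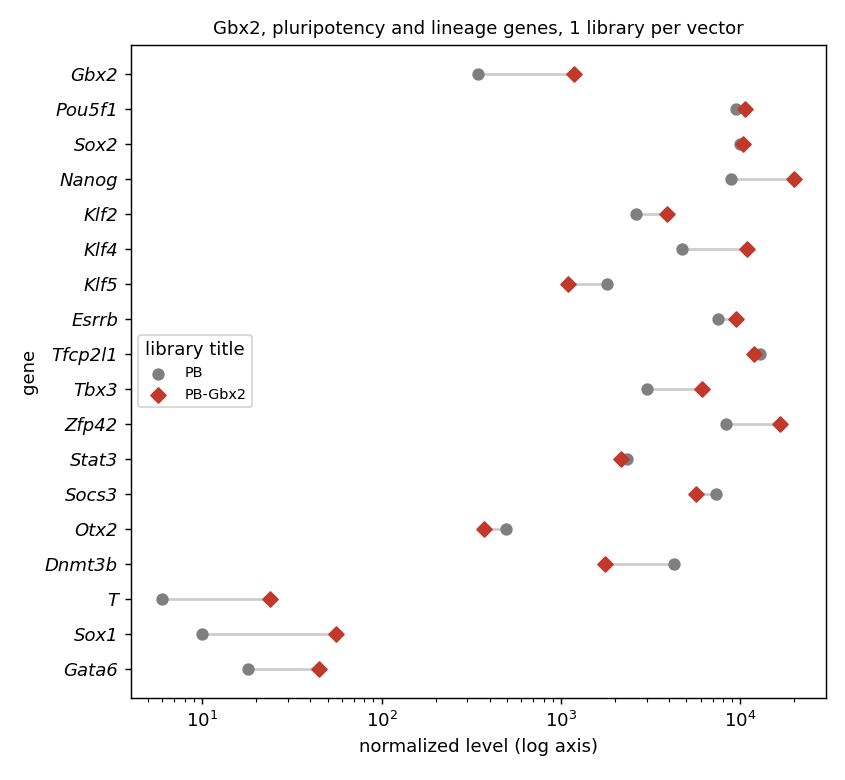
Normalized level (log axis) of Gbx2 and of the pluripotency and lineage genes chosen in advance, in the PB library (grey circles) and the PB-Gbx2 library (red diamonds), 1 library each, with a line joining both values of a gene. Gbx2, Nanog, Klf4, Tbx3 and Zfp42 stood at least 2-fold higher in PB-Gbx2 and Dnmt3b 2.44-fold lower, while Pou5f1 and Sox2 nearly coincided. The lineage genes Sox1, T and Gata6, at levels of at most 56, were also at least 2-fold higher. Among genes of similar level, Sox1 lay at percentile 99.2, but T at 89.7 and Gata6 at 92.1, inside the spread.

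Signalling targets were mixed. Among LIF and Stat3 targets (19 members, median -0.07, percentile 16.1), Klf4 was higher and Ier3 2.87-fold lower, with Sgk1 1.79-fold and Cish 1.68-fold higher. Stat3 itself (2340 and 2148) and Socs3 (7332 and 5692), the feedback inhibitor of this pathway, differed by less than 1.3-fold. Nodal, the ligand, was 2.43-fold higher (1260 to 3058), while Lefty1 (180 to 34) and Lefty2 (664 to 222), which antagonise Nodal and are induced by it, were 5.29-fold and 2.99-fold lower. The Nodal and activin list (8 members) had a median of -0.20 at percentile 5.43. Wnt and beta-catenin targets had a median of 0.09 over 11 members, with Cdx1 (34 to 122), T (6 to 24) and the cyclin Ccnd1 (670 to 1380) at least 2-fold higher and Notum 1.66-fold higher. FGF and ERK targets had a median of -0.04 over 17 members, with Ier3 and Etv1 (448 to 221) at least 2-fold lower, Phlda1 1.69-fold lower and Spry2 1.78-fold higher. BMP and Id targets had a median of 0.10 over 9 members, and Id4 (34 to 111) alone passed 2-fold. Hey1, Smad6 and Bambi differed by at most 1.41-fold. These last 3 medians lay inside the middle 95% of random lists.

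Several groups of metabolic genes were lower in PB-Gbx2. Every one of the 21 listed genes of cholesterol synthesis and uptake was lower in PB-Gbx2, 5 of them at least 2-fold, among them Fdps (185 to 68), Lss (2863 to 1203), Cyp51 (1398 to 603) and Msmo1 (2368 to 1036). The list median was -0.78, below all 10000 random lists. Of 22 hypoxia and glycolysis genes, 19 were lower and Slc2a3 alone was higher (1.30-fold). Bnip3 was 3.71-fold, Car9 2.36-fold, Tpi1 2.19-fold and Pgk1 2.02-fold lower, and Ldha 1.97-fold. The median was -0.57, below all random lists. Gapdh sat at the shared top value of 70328 in both libraries, where the scale cannot show a difference. ATF4 and unfolded protein response genes were lower on balance as well, with 18 of 22 below 0 and a median of -0.59, again below all random lists. The 4 members above 0 were Dnajb9 (1.57-fold higher), Sesn2 (1.36-fold), Xbp1 (1.09-fold) and Asns (1.05-fold). Slc7a11, Chac1 (114 to 34) and Ddit3 (552 to 240) were at least 2-fold lower, and Psat1, of serine synthesis, 1.96-fold, whereas Atf4 itself differed by 1.09-fold and the chaperone Hspa5 was 1.29-fold lower. Oxidative phosphorylation genes differed little: none of 26 reached 2-fold, 19 lay above 0 and 6 below, and the median was 0.13 at percentile 99.2. The largest ratios there were those of Cox5a (1.35-fold), Cox7b (1.34-fold), Ndufa2 (1.27-fold) and Cox5b (1.26-fold).

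**Figure D2:**
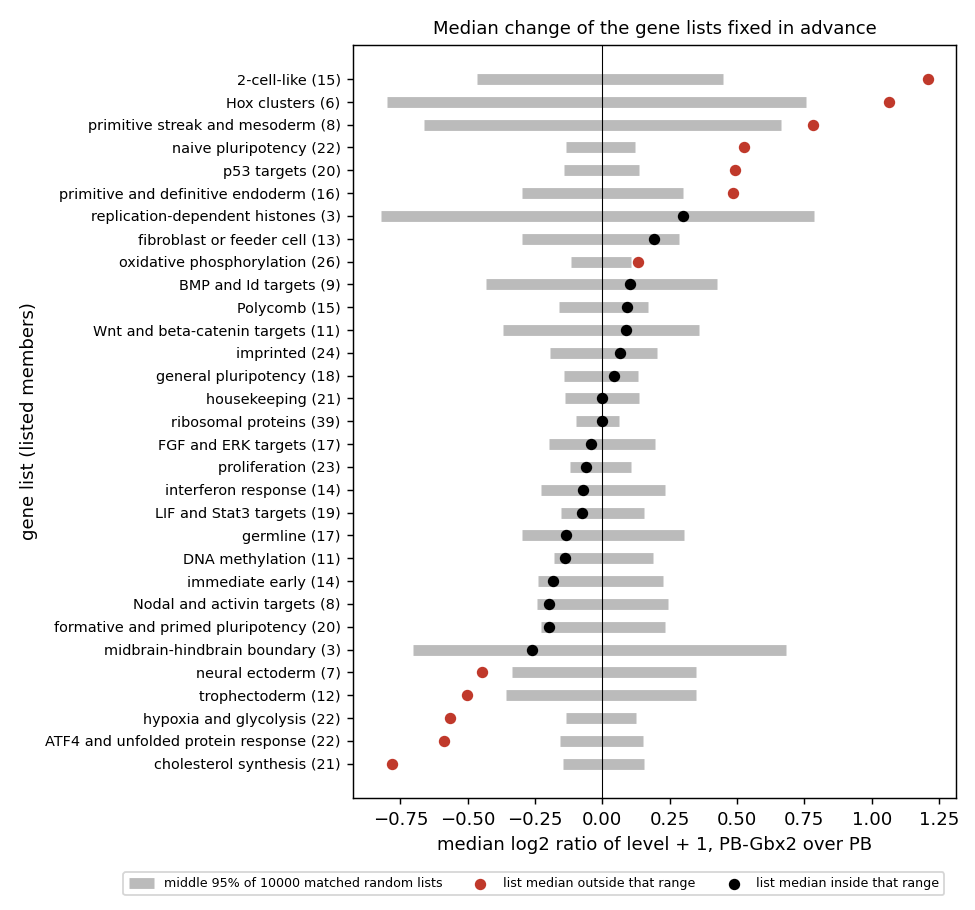
Median log2 ratio of level + 1, PB-Gbx2 over PB, for 31 gene lists fixed in advance (dots, with the number of listed members in brackets), against the middle 95% of 10000 random lists matched on level (grey bars). Of these medians, 7 lay above their bar and 5 below, led by 2-cell-like genes at 1.21 and cholesterol synthesis at -0.78.

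All 20 listed p53 targets were higher in PB-Gbx2, with a median of 0.49 that exceeded all 10000 random lists. Plk2 (820 to 2158), Ccng1 (5286 to 13646), Phlda3 (677 to 1740) and Trp53inp1 (5293 to 10938) were at least 2-fold higher. Cdkn1a, the p21 cell cycle inhibitor, was 1.51-fold and Mdm2 1.65-fold higher. Proliferation genes had a median of -0.06 over 23 members, inside the random range. Ccnd1 was 2.06-fold higher, Mki67 1.54-fold and Bub1 1.32-fold lower, and Tyms 1.24-fold higher.

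Genes of the 2-cell-like state, a rare state of these cultures, were higher in PB-Gbx2 for all 15 listed members. The median was 1.21, above all 10000 random lists, and 10 members were at least 2-fold higher. The levels were low throughout: Tmem92 went from 20 to 164, Zscan4c from 98 to 228, Usp17lb from 14 to 84, Usp17la from 13 to 74 and Usp17le from 26 to 112. The Zscan4 and Usp17l genes are families of near-identical copies, so the split of reads among their members is uncertain.

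Markers of differentiated lineages differed in direction. The primitive streak and mesoderm list (8 of 18 genes listed) had a median of 0.78 at percentile 98.9, with 6 members above 0 and 1 below. The receptor Kdr (24 to 226), T and Snai1 (76 to 154) were at least 2-fold higher, and Tbx20 stood at 12 and 22. The endoderm list (16 listed members) had a median of 0.49 at percentile 99.9, with Foxa1 (4 to 24), Gata6 (18 to 45) and Cxcr4 (45 to 101) at least 2-fold higher and Pdgfra 1.98-fold. The trophectoderm list went the other way, with 5 of 12 members at least 2-fold lower and a median of -0.50 at percentile 0.39. Without its 4 keratins, left out after the values were seen, the median was -0.32 at percentile 6.56, inside the random range. The 5 were the keratins Krt7 (43 to 4), Krt19 (377 to 54), Krt8 (532 to 225) and Krt18 (363 to 164), which are epithelial genes in general, and Bmp8b (105 to 34). In all, 9 members lay below 0 and 3 above: Esx1 (2.16-fold higher), Tfap2c (1441 to 2439) and Eomes (128 to 215). The neural ectoderm list (7 members) had a median of -0.45 at percentile 0.78, but a mean of 0.13: Elavl3 (1.77-fold) and Tubb3 (1.65-fold) were lower, and Nes (1.81-fold) and Sox1 (10 to 56) higher. The Sox1 locus carries a reporter in this line. Of the midbrain-hindbrain boundary genes, where Gbx2 acts in the embryo, 3 of 16 were listed (En2 at 49 and 148, Fgf17 at 120 and 100, and Otx2), with a median of -0.26 inside the random range. The 6 listed Hox genes had a median of 1.06 at percentile 99.5, on levels of at most 63. They included Hoxd13 (12 to 36), Hoxb13 (16 to 47), Hoxc4 (18 to 47) and Hoxb9 (36 to 63).

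**Figure D3:**
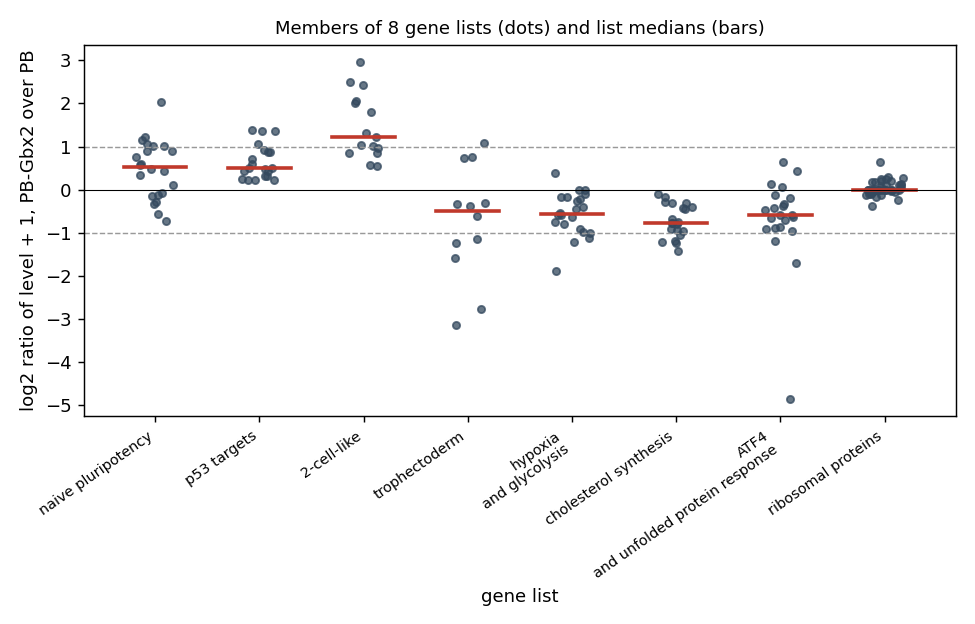
Log2 ratio of level + 1, PB-Gbx2 over PB, of each listed member (dots) of 8 gene lists, with the list median (red bar) and dashed lines at 2-fold. All p53 targets and 2-cell-like genes lay above 0 and all cholesterol synthesis genes below, while ribosomal protein genes centred on 0.

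Markers of fibroblasts, the usual feeder cells, had a median of 0.19 over 13 members at percentile 90.6. Fn1 was 2.62-fold higher (26866 to 70328, the shared top value) and Thbs1 went from 16 to 38, while Col1a1 was 3.67-fold (132 to 36) and S100a6 3.04-fold lower (435 to 143). The remaining lists also lay inside the middle 95% of random lists. Germline genes had a median of -0.14, with Stra8 1.71-fold lower, Taf7l 1.64-fold and Asz1 1.67-fold higher, and Tex101 at 11 and 22. Immediate early genes had a median of -0.18, with Cyr61 (42 to 130), Ctgf (108 to 225) and Jun (60 to 124) higher and Ier3 lower. Polycomb genes had a median of 0.09, with Suz12 1.58-fold, Pcgf2 1.41-fold and Kdm2b 1.28-fold higher and Ezh1 1.29-fold lower. Imprinted genes had a median of 0.06, with Kcnq1ot1 (336 to 126) and Cdkn1c (734 to 276), neighbours in one imprinted domain, lower and Peg12 (14 to 78) and Dlk1 (6 to 20) higher. Interferon response genes had a median of -0.07, with Ddx58 2.30-fold and H2-K1 2.04-fold lower, Psmb9 1.90-fold lower and Oas1a 2.02-fold higher. Replication-dependent histones had 3 listed members, Hist1h4i (22 to 66), Hist1h1c (502 to 246) and Hist1h2bc (99 to 122), and a median of 0.30. Ribosomal protein genes had a median of 0.00 over 39 members, none of which passed 2-fold, and their extremes were Rpl4 (1.56-fold higher, at the shared top value), Rpl7 (1.30-fold lower), Rps9 (1.22-fold higher) and Rps3 (1.20-fold higher). Housekeeping genes had a median of 0.00 over 21 members, with Pgk1 and Hprt (29 to 14) at least 2-fold lower and B2m 1.55-fold higher.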

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

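Both rescalings of the PB-Gbx2 library moved the log2 ratios by at most 2e-05, since the deposited values already share one distribution, a minimum level of 5 or none changed no gene, and a single symbol is repeated, so these settings and the highest row per symbol say nothing about stability. Nor does a pseudocount of 0.1 for the counts, as on whole numbers it sets the same 2-fold cutoff as 1. The trimmed mean still dropped 12 of the 746 higher genes, those exactly on the cutoff. A 1.5-fold threshold gave 1684 genes higher and 1770 lower in PB-Gbx2. A minimum level of 100, chosen after seeing the data, gave 269 and 259. A pseudocount of 5 kept both counts within 1.5 times the reported ones. The 12 list medians outside the random range kept their direction and stayed outside it under every alternative run but 1: without keratins the trophectoderm median was -0.32, inside it. For all lists, 148 of 155 results under the other settings kept their side of the range. The other 6, like this one under settings chosen after seeing the data, moved outside it. At a minimum level of 100 the medians were -0.32 for the formative and primed list, 0.50 for Wnt and beta-catenin targets and -0.28 for interferon response genes. With GC and length trends removed they were -0.23 for the formative and primed list and -0.38 for immediate early genes, and without members at 10000 or more -0.29 for Nodal and activin targets. The Hox and histone lists had under 3 members at a level of 100 and were not run there. Of 730 results for single genes, 28 moved by more than 1.5-fold, all with another pseudocount, and no named gene past 2-fold turned direction. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth is unknown, and the log2 SD was 1.15 in the lowest of 10 groups of genes by level.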

Other observations

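The tests of the culture behind each library, of differentiated cells of every kind and of chance among weakly listed genes were chosen after the results were seen, as were the 3 gene lists of the next paragraph and the settings that remove GC and length trends, leave out genes at 10000 or more, leave out keratins, or set a minimum level of 100.

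Genes of fatty acid synthesis and desaturation were lower together with those of cholesterol synthesis. The list was drawn up because Scd1 (2.70-fold lower) and Scd2 (2.34-fold lower) were seen first, so it is described without random lists. Of the 12 other members, 11 were lower in PB-Gbx2, with a median log2 ratio of -0.59. Acaca (1621 to 866) and Srebf1 (2208 to 1371) went the same way, and Elovl6 the opposite way (3478 to 5541). Fatty acid oxidation genes had a median of 0.12 over 14 members, with Slc25a20, which prompted that list, as the single member past 2-fold. In the betaine and methionine cycle, Bhmt and Dmgdh, which prompted the list, and the paralog Bhmt2 (34 to 222) were higher and Gnmt lower (182 to 86). The list median was 0.17 over 11 members, with 6 above 0 and 5 below. The other 7 members lay within 2-fold, so Bhmt, Dmgdh and Bhmt2 do not show a change of the pathway as a whole. Bhmt and Bhmt2 are neighbouring paralogs, and the table does not say how shared reads were split.

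Hprt stood at 29 and 14, against a median level of 3445 over the housekeeping list. The parental line of 46C, E14Tg2a, carries a deletion at Hprt, so its ratio says little about housekeeping genes.

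The hypoxia and glycolysis, cholesterol synthesis, and ATF4 and unfolded protein response lists were each lower on balance in PB-Gbx2. With GC and length trends removed, the highest of the 3 list medians was -0.57, and without members at 10000 or more it was -0.54. All 3 medians stayed below the 2.5th percentile of random lists both times, which argues against GC or length bias as the whole cause. Leaving out members at 10000 or more took the glycolysis list from 22 to 13 members and the ATF4 list from 22 to 21. The cholesterol list kept all 21. That setting thus argues against the coarse steps of the highest values as the whole cause for glycolysis, and it hardly touched the other lists. An effect of Gbx2 and the state of the single culture behind each library (density, medium or oxygen) cannot be told apart, because there is 1 library per group. These pathways respond to culture conditions, so either may account for the difference.

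The higher 2-cell-like genes could be a single gene family counted many times through shared reads. The 5 Zscan4 members were summed (275 to 570), as were the 4 Usp17l members (82 to 373). The median over 8 values was then 1.18, above 9997 of 10000 random lists. All members outside these families were higher, so this median would stay above 0 whatever the family sums were. The summing by itself thus decides little. Outside these families Tmem92, Gm4340 (7 to 31) and Gm5662 (114 to 283) were at least 2-fold higher. Zfp352 (18 to 33), Sp110 (46 to 84) and Arg2 (30 to 44) were higher by less than 2-fold. That the members outside the families were higher argues against shared reads within these families as the whole cause. Apart from Tmem92 (percentile 99.8) and Gm5662 (98.0), however, they lay inside the spread of genes of similar level. A different share of cells in the 2-cell-like state at harvest, by chance or through Gbx2, stays open and was not tested.

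Mesoderm and endoderm markers were higher on balance in PB-Gbx2 beside higher naive genes. A larger share of differentiated cells of every kind would raise the other lineages too. The higher of the trophectoderm and neural ectoderm medians was -0.45, but the neural members went both ways, with a mean of opposite sign to their median, and without keratins the trophectoderm median was -0.32, inside the random range. That explanation stays open. Chance among weakly listed genes would leave no trend at higher levels. The 10 members with a mean level of at least 100 had a median of 0.49, above 9993 of 10000 random lists. Of these, Kdr (24 to 226), Snai1 (76 to 154) and Hnf4a (99 to 174) reached that mean only through the PB-Gbx2 library. The members also come from the lists whose medians prompted the test, so it cannot decide about chance. The test was first planned on the 12 members that reached 100 in either library (median 0.63), a filter that favours genes that changed, and that version is not used. Random lists treat genes as unrelated. A small fraction of cells of 1 lineage may contribute, and with 1 library per group the vector is confounded with the culture here too.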
